A study of Homo sapiens with 2 samples.

How the data were processed

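Messenger RNA levels were measured in 2 samples of a human lymphoblastoid cell line, a B-cell culture made immortal with Epstein-Barr virus (EBV). The labels put both samples in 1 group, as replicates 1 and 2. The sample titles write the line as GM06690, whereas the growth protocol writes GM06990; both samples carry both spellings, so the grouping is not affected. The cells grew in RPMI1640 medium with fetal calf serum, per the labels' protocols. Total RNA was extracted with QIAzol and the miRNeasy kit, labelled with biotin by the Affymetrix One-Cycle procedure, and hybridised to 1 Human Genome U133 Plus 2.0 array per sample.

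The values deposited by the authors are probe set intensities, 1 per probe set and array. They were made with RMA (background correction, quantile normalization between arrays and a summary over the probes of a set), per the submitters' processing notes, and the RMA version is not given in the sources used here. RMA usually returns log2 values; these ran from 6.29 to 33093 and are therefore on a linear scale, and their log2 was taken here. The sorted log2 values of the 2 arrays differed by a median of 0.01 and by at most 0.14, so the arrays share nearly the same distribution, and a change in the total amount of messenger RNA per cell could not be seen in them. RMA gives no detection call. Values of 36289 probe sets were used, and control probe sets and further probe sets of the array design were not analysed here. The probe sets used are the first in the order of their identifiers, so a gene can have more probe sets on the array than were used. A gene counted as not above background, such as ESCO2 with 1 probe set or BCL6 with 2, was so by the probe sets used. The precision is limited by the number of arrays, and nothing in the labels says that the replicates came from separate cultures, so the spread between them may be technical.

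Probe sets were named from the platform annotation, with symbols updated by Entrez ID from a RefSeq gene table (assembly GRCh38.p14). Of the probe sets, 29493 had 1 gene symbol, 1407 had several and 5389 had none; 29461 of those with 1 symbol were matched by Entrez ID. Probe sets with several symbols or none named no gene. A gene was represented by its probe set with the highest mean log2 value over both arrays, which gave 16684 genes, of which 7340 had at least 2 probe sets. Genes on chromosome Y and XIST were left out. The files name no genome build. The gene table served for names and for the order of genes along the 22 autosomes (16062 genes). Its positions also defined the pairs of genes that overlapped or lay close together, and no coordinates are given.

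A background level was set on each array as the 95th percentile of 81 measured genes restricted to tissues such as liver, brain, muscle or eye. It was 5.70 on the log2 scale (intensity 52.1) for replicate 1 and 5.69 (intensity 51.5) for replicate 2. A gene was counted as above background when it exceeded this level on both arrays. By construction about 5% of the reference genes lie above it, and a gene not above it may still be transcribed.

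The gene lists, the rule for named genes, the background level and most of the other settings tried were fixed before the data were examined. There were 30 lists with 697 distinct genes, of which 615 were measured, plus all measured olfactory receptor genes. Genes were named by this rule: the first 3 measured members of each list in the order written; the members above background in the lists of other cell types, HOX genes and tissue-restricted genes (at most 5 per list, those furthest above); the members not above background in the other lists (at most 5, in the order written); and the 10 genes that differed most between the arrays in each direction among genes above background on at least 1 array. Further genes named as the exceptions in a count, or as examples, were chosen after their values were seen.

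With 1 group there is no contrast between conditions, so no test between groups was run and no p-values are given. Agreement between the arrays was described by Pearson r and Spearman rho across probe sets, by the SD of each pair of log2 values, and by the number of genes differing by more than 1 on the log2 scale. A list's median signal was placed among the medians of 10000 random gene lists of the same size. Because probe sets differ in affinity, these percentiles describe the signals of the chosen probe sets and are not ranks of transcript abundance. The median difference between the arrays over a list's members above background was placed among 10000 random lists matched on mean signal in 20 bins. Differences seen by the 2 brightest probe sets of a gene were correlated across genes and compared with 1000 shuffled pairings. The signals of genes a fixed number of places apart along an autosome were compared by Spearman rho, with 1000 shuffles of the signals within each chromosome; pairs whose symbols share the letters before their first digit were left out, since many belong to a gene family. The share of genes above background per autosome carries a 95% Wilson interval, which covers counting error only and treats genes as independent, which neighbouring genes are not.

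Alternatives were a background at the 99th or 75th percentile, the mean of all probe sets of a gene, probe sets without the suffixes _x_at and _s_at (which can detect several transcripts), either array in place of both, each array left out, further scalings of the arrays (median centring, a second quantile normalization, a loess curve with a span of 0.3), and a smaller minimum difference. For neighbouring genes, 4 more alternatives were chosen after seeing the data: protein-coding genes alone, the same without those suffixes, overlapping pairs left out, and pairs left out that overlapped or lay at most 1000 bases apart in the gene table. A planned correlation of each autosome's share with its gene density was not run, since the genome build of the values is not known.

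Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The calculations were tested on simulated data. In a simulated pair of arrays, 100% of 200 genes shifted by 1.5 on the log2 scale were found past a difference of 1, with 0 of the other genes. The shifted genes were drawn from those with signals well above background, and every probe set had the same noise SD. In the data the spread depended on brightness, so this checks the calculation and gives no rate for genes near background. For 7340 simulated genes, the correlation between probe sets of a gene was -0.0095 with probe set noise alone and 0.504 with gene shifts equal to that noise. A simulated series of 16062 genes with a neighbour correlation of 0.3 gave 0.28. Of 200 random lists, 3.5% had a median signal outside the central 95% of random lists of the same size. The comparison of array differences with lists matched on mean signal was not tested in this way.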

Results

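The series holds gene expression arrays of an EBV-transformed lymphoblastoid line, and its title places them beside Hi-C maps, which record contacts between parts of the chromosomes. The labels give 1 group with 2 replicates, so the comparisons were between the replicates, between fixed gene lists and background, and between genes that follow each other on a chromosome. Signals below are log2 RMA signals, given as mean ± SD of the 2 arrays (n = 2). The median intensity was 33.2 in replicate 1 and 33.3 in replicate 2, and 15964 and 15992 of the 36289 probe sets lay above the background level of each array.

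Nearly every measured member of the B-cell lineage, B-cell activation and plasma cell lists lay above background. In the B-cell lineage list 21 of 24 measured genes lay above background on both arrays, among them MS4A1, which encodes the surface protein CD20 (13.19 ± 0.10), and CD79A (11.30 ± 0.03) and CD79B (9.59 ± 0.05), the signalling chains of the B-cell receptor. Further CD79B probe sets (3.70 and 4.10) were not above background. The members not above background were CD72 (4.62 ± 0.53), BANK1 (5.79 ± 0.41) and POU2F2 (5.50 ± 0.04). BANK1 exceeded the level in replicate 2 alone. All 25 measured genes of B-cell activation and NF-kB signalling lay above background, including EBI3 (10.76 ± 0.05), the activation marker CD83 (10.45 ± 0.08) and the adaptor TRAF1 (11.11 ± 0.01). All 13 measured plasma cell genes did so too, among them the transcription factors PRDM1 (8.46 ± 0.23) and XBP1 (11.81 ± 0.01) and the surface proteoglycan SDC1 (9.07 ± 0.02).

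Of the germinal centre genes 4 of 11 were above background. LMO2 was above (8.31 ± 0.11), whereas the repressor BCL6 (4.19 ± 0.20), MME, which encodes CD10 (5.65 ± 0.07), RGS13 (5.62 ± 0.18), S1PR2 (3.79 ± 0.09) and SERPINA9 (5.88 ± 0.46) were not above on both arrays. MME and SERPINA9 exceeded the level in replicate 2 alone and RGS13 in replicate 1 alone. The median signal of this list stood at percentile 42.2 among random lists of its size, against 99.9 for the B-cell lineage list and 100 for both the activation and the plasma cell lists. The ribosomal protein, glycolysis and cell cycle lists also stood at 100, so a high percentile is not particular to B-cell genes. With the background at the 75th percentile of the reference genes, the germinal centre count was 8 of 11, and without _x_at and _s_at probe sets, which left fewer genes to measure, it was 4 of 6.

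Genes of antigen presentation were nearly all above background. The class II list had 13 of 14 above, including CD74, the invariant chain (13.85 with an SD under 0.01), HLA-DRA (14.23 ± 0.03) and CIITA, the master regulator of the class II genes (6.14 ± 0.10). RFXAP was not above (5.53 ± 0.02), nor were the further CIITA probe sets (5.14 and 3.82). The class I list had 16 of 16 above, including B2M (14.46 ± 0.04), the peptide transporter subunit TAP1 (11.23 ± 0.01) and TAPBP (10.29 ± 0.13). Of 19 cytokine and chemokine genes 12 were above background, among them LTA (9.20 ± 0.02), LTB (8.57 ± 0.06) and IL10 (6.25, differing by less than 0.01 between the arrays). IL6 (4.59 ± 0.08), IL12B (5.72 ± 0.44), CXCL8 (4.46 ± 0.15), IL1B (5.41 ± 0.19) and IL2 (4.16 ± 0.11) were among the 7 that were not, IL12B exceeding the level in replicate 1 alone. The median signal of the cytokine and chemokine list stood at percentile 53.8 among random lists of its size, so it did not stand out from them. Of 23 interferon-stimulated genes 22 were above background, including MX1 (12.43 ± 0.04), ISG15 (12.22 ± 0.03) and IFIT1 (10.08 ± 0.12), and IFI27 (5.75 ± 0.10) exceeded the level in replicate 2 alone.

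Markers of other cell types were mostly at background. Of 21 T-cell genes 3 lay above it: the kinase LCK (9.63 ± 0.04), the transcription factor GATA3 (8.48 ± 0.04) and CD6 (5.91 and 6.09 on the arrays). Both LCK probe sets were above background, but 1 of 3 for GATA3 and 1 of 7 for CD6. CD3D (4.94 ± 0.21), CD3E (4.49 ± 0.04) and CD3G (4.50 ± 0.09), which encode the CD3 chains of the T-cell receptor complex, were not above background. The NK-cell list had 0 of 14 above, with NCAM1 at 4.84 ± 0.07, KLRD1 at 4.13 ± 0.08 and NKG7 at 4.18 ± 0.07. The myeloid list had 1 of 18 above, VCAN (5.85 ± 0.06, by 1 of 5 probe sets). CD14 (3.77 ± 0.07), LYZ (3.72 with an SD under 0.01) and CSF1R (3.85 with an SD under 0.01) were below background. The erythroid and megakaryocyte list had 1 of 12 above, HBB (6.17 ± 0.24, by 1 of 4 probe sets), whereas ALAS2 (4.44 ± 0.18) and EPOR (5.37 ± 0.09) were not. Each of these last 3 counts depended on 1 array: without replicate 1 the myeloid count was 2, with S100A9, and without replicate 2 the NK-cell count was 1, with PRF1, and the erythroid count was 2, with HBD. With the level at the 75th percentile of the reference genes, the T-cell, NK-cell, myeloid and erythroid counts were 8 of 21, 3 of 14, 3 of 18 and 6 of 12. Without _x_at and _s_at probe sets they were 3 of 17, 1 of 10, 1 of 17 and 3 of 8.

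Stromal and epithelial genes were also mostly at background, with 4 of 15 fibroblast genes and 2 of 14 epithelial genes above it. The fibroblast genes above background were FBN1, which encodes fibrillin (8.67 ± 0.11), SPARC (7.72 ± 0.10), COL1A1 (7.24 ± 0.15) and DCN (5.80 ± 0.01), whereas the collagen genes COL1A2 (5.04 ± 0.08) and COL3A1 (3.87 ± 0.17) were not. Both FBN1 probe sets were above background, against 2 of 5 for COL1A1, 1 of 2 for SPARC and 1 of 4 for DCN. The epithelial genes above background were CDH1, which encodes E-cadherin (7.01 ± 0.05), and ELF3 (6.93 ± 0.11), each by 1 of 2 probe sets. EPCAM (3.88 ± 0.14) and KRT8 (5.19 on both arrays) were not. Among the 81 tissue-restricted genes that set the level, KRT10 (11.24 ± 0.08), SFTPB (6.74 ± 0.07), TNNT3 (6.28 ± 0.06) and HPX (5.83 ± 0.02) exceeded it, and ALB (3.93 ± 0.08), GFAP (4.25 ± 0.03) and ACTA1 (3.85 ± 0.03) did not. None of the 67 measured olfactory receptor genes did, against 11 of 67 with the level at the 75th percentile and 5 of 59 without _x_at and _s_at probe sets. These small counts depended on the level and the probe sets: with probe sets ending in _x_at and _s_at left out, 0 of 9 fibroblast genes and 1 of 8 epithelial genes were above background, and with the level at the 75th percentile the counts were 7 of 15 and 7 of 14.

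The HOX genes, which encode developmental transcription factors in 4 clusters, were above background in 6 of 25 cases. These were HOXB2 (8.66 ± 0.15), HOXB7 (7.86 ± 0.03), HOXC4 (7.23 ± 0.07), HOXC6 (7.62 ± 0.23), HOXC11 (5.98 ± 0.10) and HOXC5 (5.78 ± 0.11). By cluster, 2 of 9 measured HOXB genes and 4 of 8 HOXC genes were above background, against 0 of 7 HOXD genes and 0 of the 1 measured HOXA gene. HOXB1 (4.08 ± 0.15) and HOXD1 (4.62 ± 0.01) were below it. The order of the clusters depended on the level: at the 99th percentile of the reference genes the count was 2 of 25, HOXB2 and HOXB7, with 0 of 8 in HOXC, and at the 75th it was 10, with 4 of 9 in HOXB, 5 of 8 in HOXC and 1 of 7 in HOXD.

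**Figure D1:**
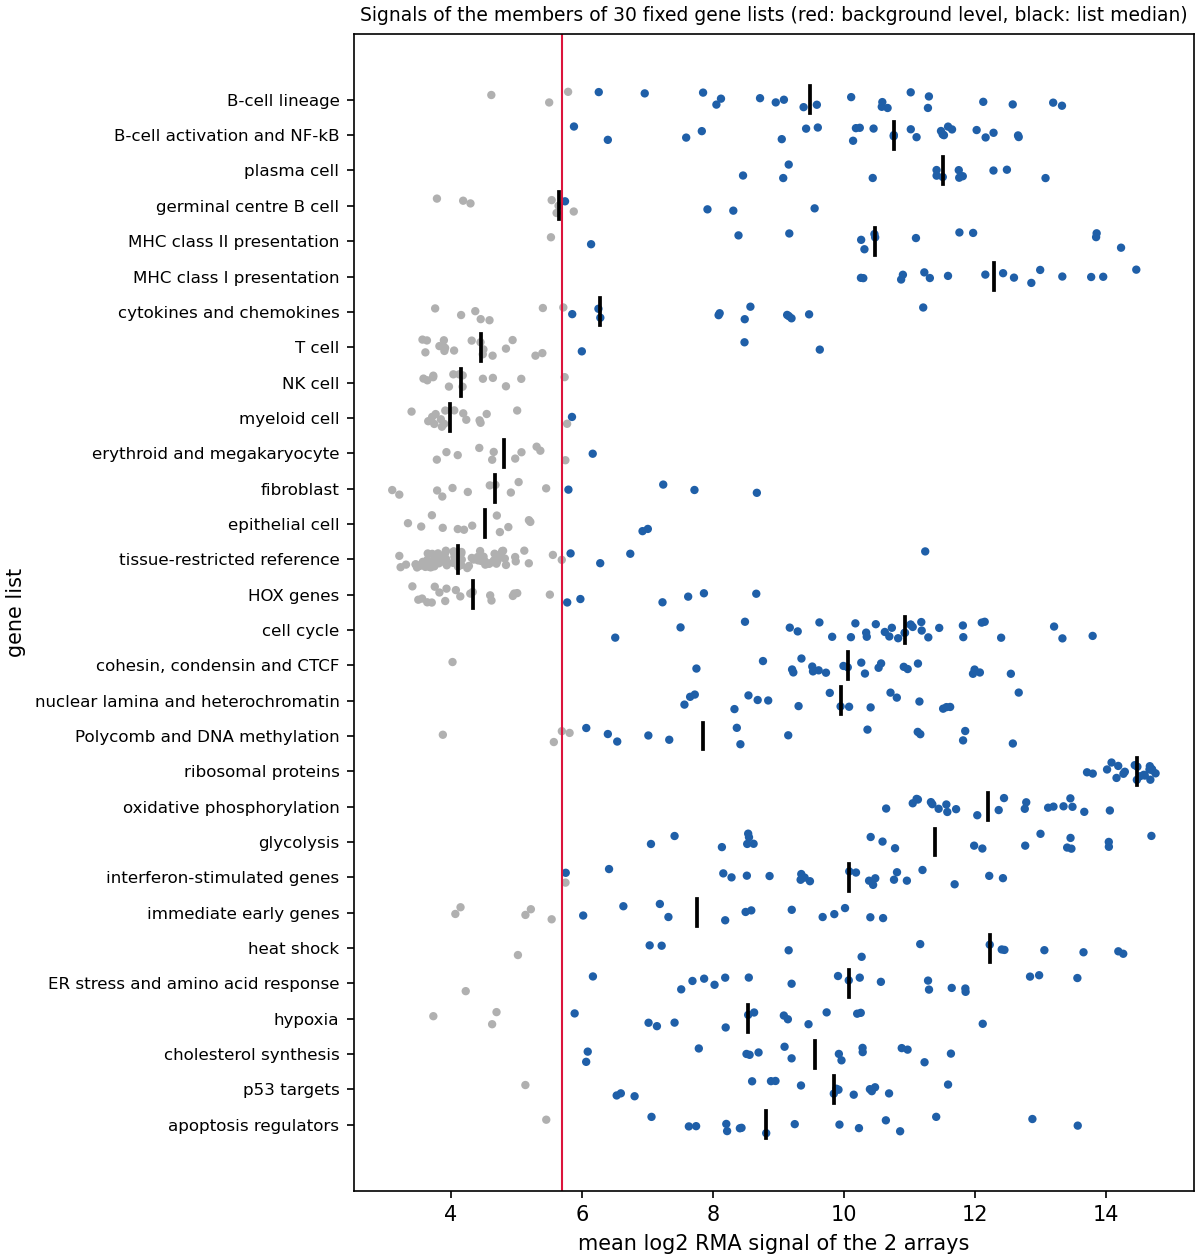
Mean log2 RMA signal of the 2 arrays (x axis) for each measured member of the 30 fixed gene lists (y axis, 1 line per list; vertical scatter within a line has no meaning). Blue points were above background on both arrays and grey points were not, the red line is the mean background level of the arrays (5.69), and black bars are list medians: the T-cell, NK-cell and myeloid medians lie left of the red line and those of the B-cell lineage, activation and plasma cell lists to its right.

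Genes of proliferation and of chromosome structure were above background in nearly every case. All 33 cell cycle genes were, including MKI67 (10.49 ± 0.05), TOP2A (12.40 ± 0.02) and CDK1 (11.82 ± 0.02). Of 23 genes of cohesin, condensin and CTCF 22 were, among them CTCF, which binds at the borders of chromosome loops (10.53 ± 0.06), and the cohesin subunits RAD21 (12.07 ± 0.08) and SMC3 (11.13 ± 0.02); the cohesin acetyltransferase ESCO2 was not (4.03 ± 0.01). All 19 genes of the nuclear lamina and heterochromatin were, including LMNB1 (10.08 ± 0.17), LMNA (8.84, SD under 0.01) and LBR (11.62 ± 0.04). The Polycomb and DNA methylation list had 14 of 18 above, with EZH2 (10.36 ± 0.01), SUZ12 (11.13 ± 0.04) and the maintenance methyltransferase DNMT1 (11.16 ± 0.02). Its members not above background were CBX2 (5.70 ± 0.19), the de novo methyltransferase DNMT3B (5.81 ± 0.20), TET1 (3.88 ± 0.14) and TET2 (5.57 ± 0.50). CBX2 and DNMT3B exceeded the level in replicate 2 alone and TET2 in replicate 1 alone, and at the 99th percentile of the reference genes the Polycomb and DNA methylation count was 9 of 18.

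Metabolic lists were wholly above background: 22 of 22 genes of oxidative phosphorylation, such as NDUFA9 (11.56 ± 0.01), SDHA (11.05 ± 0.14) and COX4I1 (13.35, SD under 0.01), 20 of 20 of glycolysis, such as HK2 (8.14 ± 0.05), PKM (12.11 ± 0.07) and LDHA (14.04 ± 0.04), and 16 of 16 of cholesterol synthesis, such as SQLE (10.29 ± 0.09), HMGCS1 (9.09 ± 0.05) and IDI1 (11.23 ± 0.03). All 20 ribosomal protein genes were above background too, including RPL3 (14.47 ± 0.03), RPS6 (14.57 with an SD under 0.01) and RPL6 (14.08 ± 0.02), and 7 of the 9 that could be measured without _x_at and _s_at probe sets. Ribosomal protein and HLA genes have near-identical copies that their probes may share, so their single values are uncertain.

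Of the immediate early genes, which respond to stimulation within minutes, 13 of 18 were above background. FOS (4.07 ± 0.12), FOSB (4.15 ± 0.01), NR4A1 (5.22 ± 0.10), NR4A2 (5.54 ± 0.02) and NR4A3 (5.14 ± 0.21) were not above, whereas EGR1 (6.63 ± 0.34) and JUN (8.59 ± 0.01) were. The dimmer EGR1 probe set (5.02) was not above background. Heat shock genes were above in 12 of 13 cases, such as DNAJB1 (9.16 ± 0.07), HSP90AA1 (14.19 ± 0.03) and HSPH1 (12.22 ± 0.04), the exception being the inducible HSPA6 (5.03 ± 0.10). Of the ER stress and amino acid response genes 20 of 21 were above, including DDIT3 (7.69 ± 0.17), the chaperone HSPA5 (13.56 ± 0.03) and ATF4 (12.98 ± 0.02) but not VLDLR (4.23 ± 0.21). Hypoxia genes were above in 14 of 17 cases, such as VEGFA (9.08 ± 0.04), BNIP3 (10.20 ± 0.05) and BNIP3L (9.46 ± 0.12), with NDRG1 (4.63 ± 0.21), P4HA2 (4.70 ± 0.27) and PFKFB4 (3.73 ± 0.11) not above. The p53 targets were above in 16 of 17 cases, including CDKN1A (10.42 ± 0.09), MDM2 (10.15 ± 0.14) and BAX (9.84 ± 0.19) but not GDF15 (5.14 ± 0.09). Apoptosis regulators were above in 16 of 17 cases, including BCL2 (9.93 ± 0.02), MCL1 (11.41 ± 0.01) and BCL2L1 (8.22 ± 0.08) but not CASP10 (5.46 ± 0.06). The median signals of the immediate early, hypoxia and apoptosis lists stood at percentiles 85.55, 94.6 and 97.3 among random lists of their size. Each lay within the central 95% of those lists.

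Across all genes, 8693 of 16684 (52.1%) were above background on both arrays and 250 on 1 array only. Of all 16684 genes, 1285 had a mean signal less than 0.5 from the mean background level on the log2 scale, above or below it. Probe sets of a gene did not always give the same call: of 296 list genes with at least 2 probe sets, 128 had every probe set above background, 89 had none and 79 had some.

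The replicates differed little. Of the 8943 genes above background on at least 1 array, 3 differed by more than 1 on the log2 scale: ZKSCAN7, a zinc finger protein gene, with a difference of -1.10 (replicate 2 minus replicate 1), OCLN, which encodes the tight junction protein occludin (-1.03), and TPM1, a tropomyosin gene (-1.01). The 20 genes with the largest differences included 7 that were above background on both arrays. Among these, ZKSCAN7, LINC02381 (-0.84) and GEM (-0.83) were higher in replicate 1, and HAUS5 (0.80), VNN2 (0.79), ZNF37BP (0.76) and MYL4 (0.73) were higher in replicate 2. The other 13 were above background on 1 array only, so the size of their differences rests on a signal at background. In replicate 1 these were OCLN, TPM1, DTX2, GIMAP1, CYP7B1, C1orf115 and KCNMB3, and in replicate 2 PHLDB3, TBXA2R, STX3, EVA1B, DLL4 and STAT4. Of the 20 genes 7 had further probe sets, and in 6 of them (TPM1, GIMAP1, HAUS5, TBXA2R, EVA1B and STX3) at least 1 further probe set differed in the opposite direction. Of these opposite probe sets, only that of HAUS5 was above background on both arrays, with a difference of -0.36. Those of the other genes lay below background on both arrays, so their direction says little.

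Pearson r between the arrays was 0.997 and Spearman rho 0.987 over all probe sets. The median SD of the pair of log2 values was 0.08 over all probe sets and 0.05 over those above background. In 5 equal bins of mean signal the median SD was 0.08, 0.11, 0.12, 0.07 and 0.04 from the dimmest to the brightest. With a minimum difference of 0.58 in place of 1, 61 genes differed, 39 higher in replicate 1 and 22 in replicate 2. These values rest on 1 pair of arrays.

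**Figure D2:**
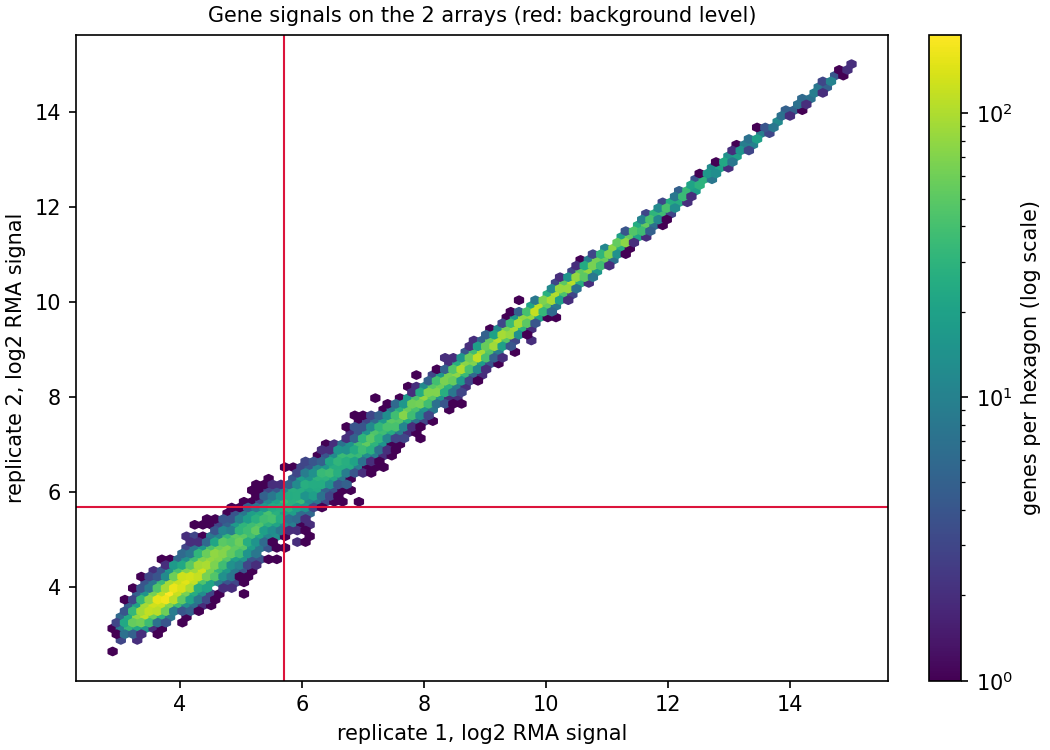
Log2 RMA signal of each of the 16684 genes in replicate 1 (x axis) and replicate 2 (y axis), with colour for the number of genes per hexagon on a log scale. Red lines mark the background level of each array (5.70 and 5.69); the cloud is narrow at high signals and wider at and below background, where most of the genes with the largest differences lie.

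Gene lists differed little between the arrays. Genes of the nuclear lamina and heterochromatin had a median difference of -0.07 (replicate 2 minus replicate 1), with 15 of 19 higher in replicate 1, such as LMNB1 (-0.24), TRIM28 (-0.22) and SUN2 (-0.19). This list was the 1 of 26 lists compared that lay outside the central 95% of its matched random lists (-0.06 to 0.03), where 1.3 lists would be outside by chance. It lay within the central 95% after a second quantile normalization (-0.04), after a loess curve was removed (-0.05) and with the mean of all probe sets (-0.03). The 4 fibroblast genes above background had a median of -0.15, within the range of their random lists, and over all measured members of that list it was 0.01. Interferon-stimulated genes had a median of -0.05, cell cycle genes -0.01 and plasma cell genes 0.02, all within the range of their random lists.

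For 3476 genes with 2 probe sets above background, the differences between the arrays seen by the 2 brightest were nearly unrelated. Pearson r across genes was 0.044 (Spearman rho 0.045), and both probe sets pointed the same way in 51.6% of genes. The shuffled pairings ranged from -0.057 to 0.051, and 2 of 1000 were as high as the observed r. Genes are not independent replicates, and this r describes these 2 arrays. Without _x_at and _s_at probe sets it was -0.028 over 1058 genes.

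Genes next to each other on the autosomes had slightly similar signals. After a gene above background, the next measured gene was above background in 59.8% of 7924 pairs, and after a gene not above it in 49.2% of 6556 pairs. Over all 14480 neighbouring pairs the Spearman rho of the signals was 0.116, while shuffles within chromosomes gave -0.026 to 0.029. At a distance of 2 genes rho was 0.050, above the highest shuffle of 0.032, and at 5 genes it was 0.021, which 10 of 1000 shuffles reached. At 10, 20, 50 and 100 genes rho was between 0.0081 and 0.0153, within the range of the shuffles. The value for direct neighbours was 0.061 among protein-coding genes without _x_at and _s_at probe sets, an alternative chosen after seeing the data, and still above its highest shuffle of 0.031. Genes are not independent, and rho is across genes within 1 cell line.

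**Figure D3:**
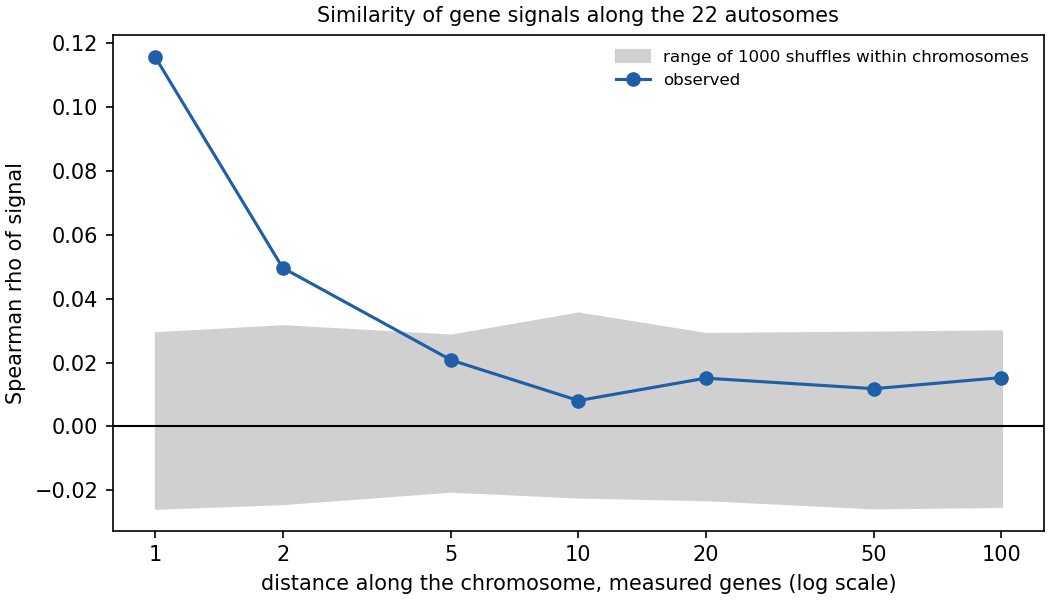
Spearman rho (y axis) between the mean log2 signals of genes a given number of measured genes apart on the same autosome (x axis, log scale). Blue points are the observed values and the grey band is the range of 1000 shuffles within chromosomes; the points at 1 and 2 genes, 0.116 and 0.050, lie above the band.

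The share of measured genes above background also varied between autosomes. It was 52.3% over all 16062 autosomal genes, 56.8% on chromosome 16 (Wilson 95% interval 53.1% to 60.4%) and 56.8% on chromosome 14 (52.5% to 61.0%), against 42.4% on chromosome 21 (35.8% to 49.2%) and 45.6% on chromosome 4 (41.9% to 49.4%). The chi-square statistic of the shares was 49.4, above the highest of 1000 shuffles over the autosomes (46.8), a comparison chosen after seeing the data. The gap between the highest and lowest share, 14.4 percentage points, was within the shuffled range (mean 8.37, highest 15.4). The shuffles treat genes as independent, which the similarity of neighbours contradicts, so they understate how much shares vary by chance.

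**Figure D4:**
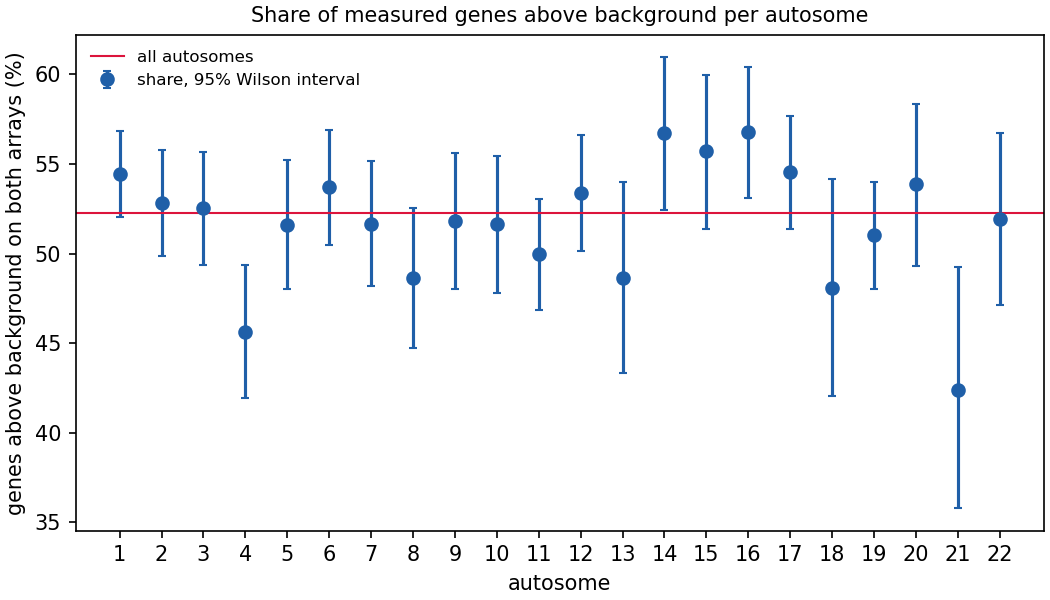
Percentage of measured genes above background on both arrays (y axis, which does not start at 0) for each of the 22 autosomes (x axis). Bars are 95% Wilson intervals, which cover counting error only, and the red line is the share over all autosomes (52.3%); the intervals of chromosomes 4 and 21 lie below that line and those of chromosomes 14 and 16 above it.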

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

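Probe sets with no gene in the annotation used entered no comparison above, yet 960 of the 5389 (17.8%) lay above the background level on both arrays, against 47.5% of the probe sets with 1 gene. Which transcripts they detect was not analysed here.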

How the results depend on the processing

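The number of genes above background stayed within 1.5 times 8693 in all 8 alternatives (6468 to 10554), and the replicate correlation was 0.997 throughout. Median centring, among these 8, shifts the signals and the level of an array alike. It could change neither this number nor the correlation. Lists with nearly every member above background changed little with the level, and the small counts of other lineages changed more. The level itself moved far, to 7.59 and 7.69 on the 2 arrays at the 99th percentile and to 4.60 and 4.65 at the 75th. At the 99th percentile of 81 genes it is interpolated between SFTPB (6.69 and 6.79) and the highest reference gene, KRT10 (11.19 and 11.29). That level, and every count at it, therefore depends on the signal of KRT10. At the 99th percentile the counts were 0 for myeloid, 0 for erythroid and megakaryocyte, 1 for fibroblast, 0 for epithelial, 1 for tissue-restricted, 2 for HOX and 9 for Polycomb and DNA methylation genes. At the 75th percentile they were 8 for germinal centre, 8 for T-cell, 3 for NK-cell, 3 for myeloid, 6 for erythroid and megakaryocyte, 7 for fibroblast, 7 for epithelial, 18 for tissue-restricted, 10 for HOX and 11 for olfactory receptor genes. With the mean of all probe sets, 1 epithelial and 1 olfactory receptor gene were above. Without _x_at and _s_at probe sets fewer members could be measured. The counts were then 10 of 10 for MHC class I, 1 of 10 for NK-cell, 3 of 8 for erythroid and megakaryocyte, 0 of 9 for fibroblast, 1 of 8 for epithelial, 7 of 9 for ribosomal, 9 of 10 for glycolysis, 5 of 6 for heat shock, 8 of 11 for hypoxia, 9 of 10 for cholesterol, 10 of 11 for p53 target and 5 of 59 for olfactory receptor genes. The background level was also set anew, from 66 reference genes, and its part in these changes was not separated. Leaving out each replicate gave 1 to 2 for myeloid, 0 to 1 for NK-cell and 1 to 2 for erythroid genes. The remaining 152 of 186 list counts were within 1.5 times the reported ones.

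The similarity of neighbouring genes (0.116) stayed above its highest shuffle in each alternative. It was 0.121 with the mean of probe sets, 0.0897 without _x_at and _s_at probe sets, 0.151 with pairs sharing a symbol stem kept, and as a phi coefficient 0.106, or 0.0849 and 0.0972 with the level at the 99th and 75th percentile. Leaving out each replicate gave 0.1148 to 0.1155. The alternatives chosen after seeing the data gave 0.0905 for protein-coding genes, 0.0614 for these without _x_at and _s_at probe sets, 0.109 without overlapping pairs and 0.0941 without pairs that overlapped or lay at most 1000 bases apart. At a minimum of 0.58, 61 genes differed between the replicates in place of 3, since the limit was lower. For list differences, 123 of 130 alternatives moved by less than the median SD of genes above background; the fibroblast median (-0.15) was among the exceptions, at 0.01 over all measured members and -0.25 with the mean of probe sets. The nuclear lamina list lay outside its random lists as deposited. It was within them in the other scalings except median centring, and with the mean of probe sets (-0.03 to -0.05), a comparison chosen after seeing the data. Median centring moves the difference of every gene by the same amount. It could not change a list's position among its random lists, and its alternatives among the 130 were bound to move little. The correlation between probe sets of a gene was 0.0310 to 0.0438 in 4 alternatives, among them median centring, which cannot change it. Without _x_at and _s_at probe sets it was -0.0275. The cause of these changes was not tested except where stated. The planned account of control probe sets and the correlation with gene density were not run. Signals close to background limit the calls, as 1285 genes had a mean signal less than 0.5 from the level, above or below it. No paired analysis was possible because the labels give 1 group.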

Other observations

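The tests on T cells, fibroblasts, single probe sets of other-lineage genes, overlapping pairs and close pairs below, and the counts of shuffles as high as a value, were chosen only after the results were seen. The design has 1 group, so no effect of a condition was tested.

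Genes of other lineages, HOX genes and tissue-restricted genes above background numbered 21, and LCK, GATA3 and FBN1 were among them. The 4 tissue-restricted genes among the 21 came from the reference set, of which about 5% exceed the level by construction. Those with at least 2 probe sets also enter the share given below. T cells in the culture as a source of the 21 genes are argued against by the whole T-cell list, with a median of 4.45 against a background of 5.69. CD3D (4.94), CD3E and CD3G also argue against it, as all were below background. Fibroblasts are argued against by a list median of 4.68 and by abundant fibroblast transcripts: the 2 probe sets of COL1A2 and the 4 of COL3A1 were all below background, and so were 3 of the 5 of COL1A1. A probe set that picks up another transcript may account for some of the genes: of 15 with at least 2 probe sets, a second was also above background in 6 (40%), such as KRT10 (3 of 3), HOXB7 (3 of 3), LCK (2 of 2) and FBN1 (2 of 2), but in GATA3 1 of 3 was, in CD6 1 of 7 and in HBB 1 of 4. This share cannot decide, and whether the cell line itself transcribes these genes stays open.

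Neighbouring genes had similar signals, which could come from related or cross-hybridising genes lying side by side. With pairs sharing a symbol stem and _x_at and _s_at probe sets left out, rho was 0.0897, and among protein-coding genes 0.0905. Each was above its highest shuffle (0.031 and 0.030), so neither those probe sets nor dim non-coding entries account for all of the similarity. With both left out, rho was lower, at 0.0614, and still above its highest shuffle (0.0314). The similarity was not measured with overlapping or close pairs left out as well. Taken alone, overlapping pairs do not account for all of it either, with rho at 0.109 once they were left out. Nor do divergent pairs with a shared promoter region: leaving out the 2838 pairs that overlapped or lay at most 1000 bases apart gave 0.0941 (highest shuffle 0.0285). The value of 0.0081 at 10 genes goes with any cause of short reach and decides nothing. Gene families under unrelated symbols and the base composition of probes were not tested, so shared regulation of neighbours is at most a hypothesis.

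The differences between the replicates could be noise of single probe sets. The correlation between 2 probe sets of a gene was 0.0438 over 3476 genes above background and 0.0310 over 7340 genes with all probe sets used. Both were far below the 0.504 simulated for gene shifts as large as the noise. That simulation covered 7340 genes with 1 noise SD for all signals, whereas the spread between the arrays depended on brightness. Both lay within the range of the shuffled pairings, but 2 of 1000 shuffles reached the 0.0438 and 1 of 1000 reached the 0.0310. Without _x_at and _s_at probe sets the correlation was -0.0275, which 812 of 1000 shuffles reached. A small part shared by the probe sets of a gene therefore cannot be excluded. After a brightness-dependent curve was removed, 0.0346 took the place of 0.0438, and 30 of 1000 shuffles reached it. Since the correlation lay in the shuffled range before the curve was removed, this test does not separate a normalization effect from noise.

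Values equal on both arrays to the last deposited digit were found in 159 probe sets (0.438%), with a median signal of 4.16 on the log2 scale, KRT8 among them.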
